A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

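The series measured RNA secondary structure in Saccharomyces cerevisiae. Per the labels' protocols, cells were grown to log phase at 23 °C, RNA was extracted with hot acid phenol, selected for polyA in 2 rounds and refolded in a buffer with 10 mM magnesium and 100 mM KCl. Per the labels' protocols, the RNA was then cleaved with RNase V1 or nuclease S1 for 15 min, fragmented by alkaline hydrolysis to about 200 nt, ligated to adapters, reverse transcribed and amplified in 18 to 20 PCR cycles. Samples were grouped by the nuclease named in their labels, as 4 RNase V1 and 3 nuclease S1 libraries. Per the design text, the authors sequenced 7 SOLiD lanes and combined them as log ratios; those values were not analysed here. The depth of each library is therefore unknown, and no precision can be derived from it.

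The values used were genome coordinates. Per the design text, the authors deposited an annotation with the gene, chromosome, start, end and feature of each entry, counted from 1. The features present were transcripts, exons, 5' UTRs and 3' UTRs, with no entry marked as an intron. How the authors set the UTR ends, which genome build the coordinates use, and which aligner was used are not given in the sources used here. Starts above ends marked the minus strand, and the strand matched the last letter of every systematic name, with 0 exceptions.

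Lengths were computed as end minus start plus 1. Introns were taken as gaps of at least 10 nt between exons of a transcript. Symbols came from the R64 reference annotation, which matched 2999 of the 3000 reading frame names. The coordinates did not follow R64: 428 of 3000 coding regions (14.3%) began with ATG and ended in a stop codon at the R64 positions, where 95% had been required. The planned comparison of GC content was therefore not run, and coordinates of the builds were not mixed. R64 was used only for symbols, for which genes are neighbours, and for sequence found by gene name and taken at R64's own coordinates. That sequence was the region upstream of start codons and, for genes with an annotated intron, the 206 gaps of at least 10 nt between R64 coding segments.

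UTR lengths of the 5' and 3' ends were compared within genes by a two-sided sign-flip permutation test of the mean difference in log2 length. Each of 15 gene lists was compared with all other mRNAs by a two-sided permutation test of the difference in mean log2 length, and for introns by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 15 lists for each outcome. The lists were cytosolic and mitochondrial ribosomal proteins, glycolysis and fermentation, proteasome subunits, chaperones, ergosterol biosynthesis, cell cycle regulators, mRNAs with known upstream open reading frames, bud-localised mRNAs, cell wall and secreted proteins, the respiratory chain and ATP synthase, histones, translation factors, DNA-binding transcription factors, and actin, tubulin and septins. Ribosomal protein lists were drawn by gene name, and the mitochondrial list includes MRP8, whose place in the ribosome is uncertain. Another 6 genes each stand on a pair of lists: RPN4, ERG2, CLN3, CLB2, TIF4631 and GCN4. RPN4 is on the proteasome and the DNA-binding transcription factor lists, so the proteasome list does not hold subunits alone. Permutation tests used 100000 resamples, and the sign-flip test of the median 10000 rather than 100000. Overlap was tested between convergent and divergent pairs of neighbouring mRNAs by permutation, with non-coding RNAs left out. Shares carry 95% Wilson intervals, which cover counting error over genes.

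The lists, tests and most alternatives were fixed before the data were examined, as was the rule for named genes: the 2 longest and 2 shortest UTRs of each list at each end, the 5 longest UTRs at each end and the 5 longest introns of all genes, the 3 longest overlaps, and 7 mRNAs with known elements. The actin, tubulin and cofilin introns and the pair IRC21 and ABF2 are named outside that rule. So are MRPL33, MRPL44, MRPL19 and ATP7, which tied in length with members it names. All of these were chosen after their values were seen. The minimum intron length, the restriction of pairs to mRNAs, 8 further alternatives and the search for splice motifs were chosen after the data had been seen. That search took the sequence GTATGT, followed by TACTAAC with more than 60 nt from the start of the first to the end of the second, in the 1000 nt upstream of each start codon, and a 5' UTR was said to reach the donor when its length was at least the distance to it less 1 nt. The alternatives were a minimum UTR length, medians, mRNAs without introns, mRNAs with both UTRs, a 50 nt overlap, and the added ones on splice motifs, exon gaps, reference neighbours and non-coding RNAs.

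The tests were tested on simulated data before use. In 100 simulations each over 2882 genes, a shift of 0.5 in log2 length gave p under 0.05 in 40 for lists of 10 genes, 58 for 20, 91 for 36 and 100 for 138. With no shift, 2 to 6 of 100 did so. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, Biopython 1.88 and matplotlib 3.10.9.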

Results

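Polyadenylated RNA from log-phase Saccharomyces cerevisiae was folded in vitro and cleaved with 1 of 2 nucleases, RNase V1, which cleaves base-paired RNA, or nuclease S1, which cleaves single-stranded RNA. The labels give 4 RNase V1 and 3 nuclease S1 libraries, which the design text describes as separate experiments. The sample titles call the starting material total RNA, whereas the source and molecule fields call it polyA RNA. The data analysed here were the annotation of yeast transcripts that accompanies the cleavage data, that is, the position of each transcript, exon and untranslated region (UTR). Cleavage values of the libraries were not analysed here, so RNase V1 was not compared with nuclease S1, the depth of each library is unknown, and no value has a replicate error. The gene was the unit of each test. Genes are not independent replicates. Standard errors (SE) reflect the spread between genes, and p-values were computed over genes, not over replicate samples.

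The annotation held 3196 transcripts on the 16 nuclear chromosomes, of which 3000 had the name of a protein-coding reading frame. The others were 118 tRNAs, 60 small nuclear or nucleolar RNAs, 14 rRNA entries, the spliceosomal RNA LSR1, the signal recognition particle RNA SCR1, the telomerase RNA TLC1 and the non-coding RNA SRG1. Both UTRs were listed for 2674 mRNAs, the 3' UTR alone for 208, the 5' UTR alone for 5, and neither for 113. The mRNAs were divided almost evenly between the strands, with 1490 on the plus strand and 1510 on the minus strand. Coding regions had a median length of 1080 nt, and the length of each was a multiple of 3.

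Yeast mRNAs carried longer 3' UTRs than 5' UTRs. The median 5' UTR was 50 nt (quartiles 30 and 94.5 nt, 2679 mRNAs) and the median 3' UTR was 106 nt (quartiles 72 and 155 nt, 2882 mRNAs). Among the 2674 mRNAs with both, the 3' UTR was the longer in 2007 (75.1%, 95% Wilson interval 73.4 to 76.7%), the 5' UTR in 657, and 10 had UTRs of equal length. The mean paired difference in log2 length was 0.97 (SE 0.029, SD 1.52), a 1.96-fold greater length at the 3' end, with a two-sided sign-flip permutation p of 1e-05, the smallest the resamples can give.

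The 5 longest 5' UTRs belonged to BMH2, which encodes a 14-3-3 protein (827 nt), BRE5, a cofactor of a deubiquitinating enzyme (712 nt), CDS1, the CDP-diacylglycerol synthase (685 nt), IPT1, a sphingolipid biosynthesis enzyme (682 nt), and URA2, the enzyme that starts pyrimidine synthesis (624 nt). The BMH2 5' UTR lay on chromosome 4 at positions 652778 to 653604, and its first base was within 1 nt of a splice donor motif followed by a branch point motif. The URA2 5' UTR, on chromosome 10 at 172365 to 172988, also reached such a pair of motifs. The 5 longest 3' UTRs were those of ABF1, a general regulatory factor that binds DNA (1274 nt, chromosome 11 at 228410 to 229683), ALG9, a mannosyltransferase (1192 nt, chromosome 14 at 234805 to 235996), SQT1, a chaperone of a ribosomal protein (1173 nt), the uncharacterised reading frame YMR209C (1045 nt) and COX15, required for heme A synthesis (1038 nt). Positions are those of the annotation, whose genome build is not given in the sources used here.

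**Figure D1:**
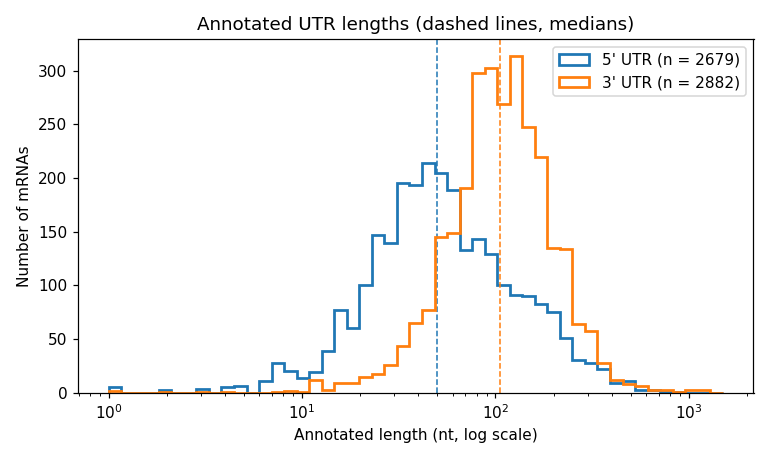
Number of mRNAs (vertical axis) by annotated UTR length in nt (horizontal axis, log scale), for 2679 5' UTRs (blue) and 2882 3' UTRs (orange). Dashed lines mark the medians of 50 and 106 nt.

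Of 7 mRNAs with well-known regulatory elements, 4 were listed. GCN4, the activator of amino acid synthesis whose translation is set by upstream open reading frames, had a 5' UTR of 571 nt on chromosome 5 (139764 to 140334) and a 3' UTR of 72 nt. CLN3, a G1 cyclin that also has an upstream reading frame, had a 5' UTR of 319 nt and a 3' UTR of 11 nt. RPS28B, which encodes a ribosomal protein that binds the 3' UTR of its own mRNA, had a 5' UTR of 13 nt and a 3' UTR of 643 nt on chromosome 12 (673337 to 673979). HAC1, the unfolded protein response factor spliced outside the spliceosome, was listed with its 252 nt intron, a 5' UTR of 68 nt and a 3' UTR of 416 nt. ASH1, URE2 and YAP1 were not analysed here.

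Whether functional classes differ in UTR length was examined with 15 gene lists. Cytosolic ribosomal protein mRNAs had shorter 5' UTRs than other mRNAs, with a median of 27 nt against 52 nt, and 105 of 134 lay below the median of the others. RPL16B (6 nt) and RPL37B (8 nt) had the shortest. RPS22B (564 nt) and RPS29A (494 nt) had the longest, and each of these long 5' UTRs began within 1 nt of a splice donor motif. Mitochondrial ribosomal protein mRNAs also had shorter 5' UTRs, with a median of 36.5 nt against 51 nt, and 33 of 46 lay below the median of the others. MRPL37 (7 nt) was the shortest of this list, ahead of MRPL20, MRPL33 and MRPL44 (8 nt each), and MRPL7 (143 nt) was the longest, ahead of MRPL31 and MRPL19 (99 nt each). The mean log2 length differed by -0.59 for cytosolic ribosomal proteins (SE 0.12, adjusted permutation p = 0.00015, which goes with the smallest p the resamples can give) and by -0.65 for mitochondrial ribosomal proteins (SE 0.16, adjusted permutation p = 0.0061). The cytosolic difference turned to 0.19 among mRNAs without annotated introns (adjusted permutation p = 0.442), and was -0.89 without the 39 genes that have both splice motifs upstream, whatever their 5' UTR length (adjusted p = 0.00015), and -0.52 with both sets left out (adjusted p = 0.079). The mitochondrial call was lost among 5' UTRs of at least 10 nt, a limit that removes the shortest ones (-0.49, adjusted permutation p = 0.0521) and for the difference of medians (-14.5 nt, adjusted p = 0.155).

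None of the other 13 lists passed an adjusted p of 0.05 for the 5' UTR. Cell cycle regulators had a median of 116 nt against 50 nt (difference in mean log2 length 1.07, SE 0.33, 9 mRNAs, adjusted permutation p = 0.0695), with CLN3 (319 nt) and CLN1 (194 nt) at the top. Bud-localised mRNAs differed by 0.86 (SE 0.38, 12 mRNAs, adjusted permutation p = 0.0743), led by MID2 (423 nt) and IST2 (247 nt). The mRNAs with known upstream open reading frames differed by 1.25 (SE 0.98, 5 mRNAs, adjusted permutation p = 0.0966). Their medians, 241 nt against 50 nt, did differ past the threshold when medians were compared (191 nt, adjusted permutation p = 0.00555). That median rests on the 5 of 8 listed members with an annotated 5' UTR. An upstream reading frame lies in the 5' UTR, so length is partly a condition of membership in this list. Respiratory chain and ATP synthase mRNAs differed by 0.45 (adjusted permutation p = 0.097), and their longest 5' UTR, that of COX4 (484 nt), also reached a splice donor motif. The differences were 0.60 for DNA-binding transcription factors, 0.34 for cell wall and secreted proteins, 0.12 for ergosterol biosynthesis, -0.02 for chaperones, -0.16 for proteasome subunits, -0.19 for glycolysis and fermentation, -0.40 for translation factors, -0.46 for histones and -0.51 for actin, tubulin and septins. Adjusted p-values of these 9 lists ran from 0.103 to 0.935.

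At the 3' end, the mRNAs of the respiratory chain and ATP synthase, the nuclear-encoded machinery of oxidative phosphorylation, stood apart. Their median 3' UTR was 214 nt against 105 nt in other mRNAs, and 32 of 36 lay above the median of the others. CYC1, which encodes cytochrome c, had the longest at 892 nt, followed by the cytochrome c oxidase subunit COX6 at 453 nt, while COX5B (34 nt) had the shortest, followed by ATP2 and ATP7 (71 nt each). The mRNAs of DNA-binding transcription factors had a median of 148 nt against 106 nt, 17 of 21 lying above, from ARG80 (49 nt) and SFP1 (52 nt) to CBF1 (590 nt) and ABF1 (1274 nt). Those of cell wall and secreted proteins had a median of 162.5 nt against 106 nt, 22 of 28 lying above, from CRH1 (58 nt) and CCW12 (60 nt) to SED1 (327 nt) and PIR3 (371 nt). The differences in mean log2 length were 0.95 for the respiratory list (SE 0.14, adjusted permutation p = 0.00015), 0.79 for transcription factors (SE 0.25, adjusted permutation p = 0.0029) and 0.57 for cell wall proteins (SE 0.13, adjusted permutation p = 0.0087). The transcription factor call was lost for the difference of medians (42 nt, adjusted permutation p = 0.053), and the annotation listed 22 of the 70 genes on that list.

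The other 12 lists did not pass the threshold at the 3' end. Histone mRNAs had a median of 159 nt, with 9 of 10 above the median of other mRNAs (0.70, SE 0.14, adjusted permutation p = 0.0654), from HTB1 (105 nt) to HHO1 (312 nt). Translation factor mRNAs had a median of 141 nt, with 27 of 36 above (0.39, SE 0.087, adjusted permutation p = 0.0555), and passed it for the difference of medians (35 nt, adjusted permutation p = 0.033). The differences were -0.06 for cytosolic and -0.11 for mitochondrial ribosomal proteins, 0.29 for bud-localised mRNAs and 0.13 for actin, tubulin and septins. They were 0.06 for glycolysis and fermentation, 0.04 for chaperones, -0.03 for ergosterol biosynthesis, -0.07 for cell cycle regulators, -0.24 for proteasome subunits and -0.55 for mRNAs with known upstream open reading frames. Adjusted p-values of these 10 lists ran from 0.239 to 0.895.

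**Figure D2:**
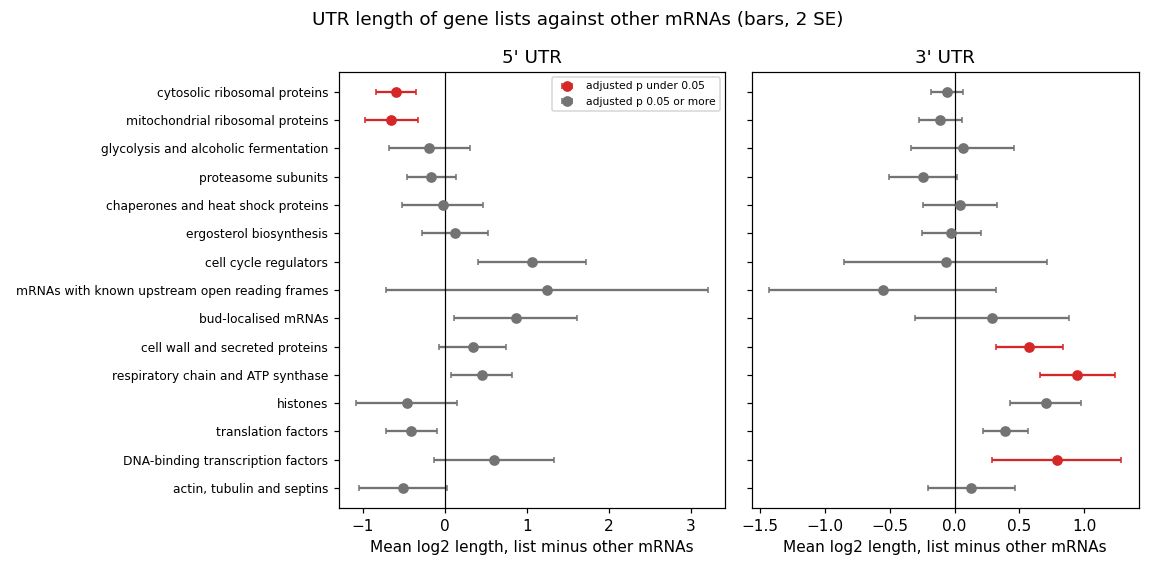
Difference in mean log2 UTR length between each of 15 gene lists and all other mRNAs (horizontal axis), for the 5' UTR (left) and the 3' UTR (right). Points are differences, bars extend 2 SE to each side, and red marks an adjusted permutation p under 0.05, as for respiratory chain mRNAs at the 3' end (0.95).

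Introns in coding regions were concentrated in ribosomal protein genes. Of 138 cytosolic ribosomal protein genes, 89 had an annotated intron (64.5%, 95% Wilson interval 56.2 to 72.0%), against 110 of 2862 other genes (3.84%, Fisher's exact test, adjusted p = 5.02e-77). Among genes of actin, tubulin and septins, 7 of 21 had an intron (33.3%, 17.2 to 54.6%), against 6.45% of other genes (Fisher's exact test, adjusted p = 0.00199). These 7 included ACT1 (actin, 308 nt), the alpha-tubulin genes TUB1 (116 nt) and TUB3 (298 nt) and the cofilin gene COF1 (179 nt). No intron was listed for glycolysis, chaperones, ergosterol biosynthesis, cell cycle regulators, mRNAs with upstream open reading frames, bud-localised mRNAs, cell wall proteins or histones. The respiratory list had 3, translation factors 2, and mitochondrial ribosomal proteins, proteasome subunits and transcription factors 1 each, and none of these 13 lists passed the threshold (adjusted p from 0.98 to 1).

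In all, 206 introns of at least 10 nt were found in 199 protein-coding genes, with a median of 254 nt. The longest was the 1002 nt intron of the RNA helicase gene DBP2 (chromosome 14, 414914 to 415915), followed by those of the mRNA export factor gene YRA1 (766 nt), the glycolytic activator gene GCR1 (751 nt), RPL27A (561 nt) and RPS19B (551 nt). The 10 nt minimum was set after 1 nt gaps had been seen.

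Neighbouring mRNAs overlapped mainly where they were transcribed towards each other. The longest overlap, 1220 nt on chromosome 11 (228464 to 229683), was that of ABF1 with KTI12, a gene of tRNA modification, and the 3' UTR of ABF1 covered 942 nt of KTI12 coding sequence on the other strand. YMR209C overlapped the mevalonate kinase gene ERG12 by 1021 nt on chromosome 13 (684865 to 685885), and ALG9 overlapped the adenylosuccinate synthase gene ADE12 by 1006 nt on chromosome 14 (234805 to 235810). Of 771 convergent pairs, 224 overlapped by at least 1 nt (29.1%, 95% Wilson interval 26.0 to 32.4%), with a median overlap of 77 nt. Of 768 divergent pairs 9 overlapped (1.17%, 0.618 to 2.21%), and of 1445 tandem pairs 24 (1.66%, 1.12 to 2.46%). The pair IRC21 and ABF2, classed as divergent, overlapped by 716 nt through a 3' UTR rather than between 5' ends. The 795 nt 3' UTR of IRC21 covered 552 nt of ABF2 coding sequence. Convergent and divergent pairs differed by 27.9 percentage points (two-sided permutation p = 1e-05, the smallest the resamples can give). Because the annotation omits many genes, the shares were also taken over pairs that are next to each other in the reference, a choice made after seeing the data: 221 of 411 convergent pairs (53.8%), 9 of 429 divergent pairs (2.10%) and 24 of 749 tandem pairs (3.20%) then overlapped.

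**Figure D3:**
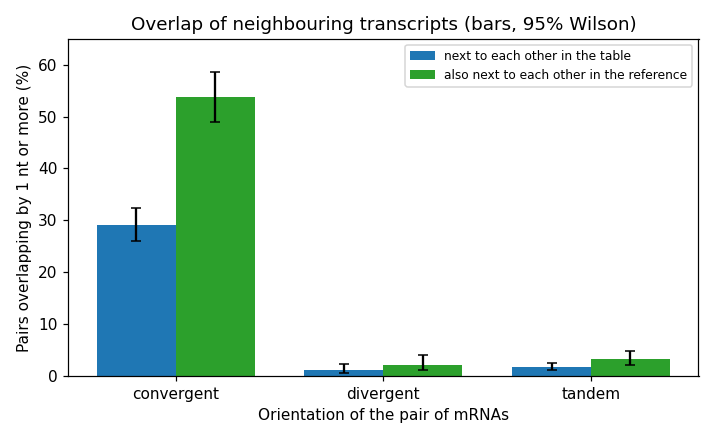
Percent of neighbouring mRNA pairs that overlap by at least 1 nt (vertical axis) by orientation (horizontal axis), for pairs next to each other in the annotation (blue) and pairs also next to each other in the reference (green). Bars show shares with 95% Wilson intervals, 29.1% and 53.8% for convergent pairs and at most 3.20% for divergent and tandem pairs.

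Across genes, 5' UTR length rose with coding length (Spearman rho 0.26, Pearson r of log2 lengths 0.24, 2679 mRNAs, permutation p = 1e-05 for each, adjusted p = 1.5e-05 for rho). The 3' UTR did not pass the threshold by rank (rho -0.03, 2882 mRNAs, permutation p = 0.0733, Pearson r -0.04, permutation p = 0.0345). Lengths of the 5' and 3' UTR of the same mRNA were weakly correlated (rho 0.12, 2674 mRNAs, permutation p = 1e-05, adjusted p = 1.5e-05). These 3 rank correlations were adjusted together.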

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

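The alternatives on splice donor motifs, exon gaps, reference neighbours and non-coding RNAs were chosen after the results had been seen. For the 5' UTR, 2 lists were shorter and 0 longer. The number of shorter lists was 1 with UTRs of at least 10 nt, 1 for medians, 1 without annotated introns, and 1 when mRNAs with splice motifs were left out as well, by either rule given here, while medians gave 1 longer list, the mRNAs with upstream open reading frames. Without annotated introns the cytosolic ribosomal protein difference turned from -0.59 to 0.19. With the 39 genes that have both motifs upstream also left out, it was -0.52, and with those whose 5' UTR reaches the donor -0.53. The latter rule can remove only long 5' UTRs, so it lowers the value by construction, but the former does not use 5' UTR length. Both removed the same 10 ribosomal protein mRNAs without annotated introns, with a median 5' UTR of 382.5 nt. The median was 27 nt in the other 37 and 25 nt in the 87 with an intron. The turn thus rested on those 10 mRNAs. Whether their 5' UTRs hold intron sequence was not settled. The rank correlation of 3' UTR with coding length passed an unadjusted p of 0.05 without intron-bearing genes (rho -0.043, permutation p = 0.0249), and the cause was not tested. The greater length of 3' than 5' UTRs held under each of 3 alternatives (log2 difference 0.89 and 0.92, median 50 nt), as did the 2 intron calls under 2 alternatives and the excess overlap of convergent pairs under 3 (24.1 to 30.2 percentage points). Leaving out donor-reaching 5' UTRs (0.99) and taking only reference neighbours (51.7 percentage points) could hardly do other than raise these values. Of the 3 longer 3' UTR lists, the respiratory and cell wall lists held under each of 4 alternatives. No paired analysis was possible because no values per library were analysed; for that reason the alternatives for RNase V1 against nuclease S1 were not run. The GC alternatives were not run either, and restricting to nuclear chromosomes removed nothing. Depth could not be weighed.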

Other observations

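The tests of splice motifs in 5' UTRs were chosen only after the result was seen, and the descriptive values on intron length, hosted RNAs, listing shares and 3' UTRs over coding sequence were also chosen after seeing the data. Introns of ribosomal protein genes were longer than those of other genes, with a median of 408 nt (91 introns) against 96 nt (115 introns, permutation p = 1e-05, the smallest the resamples can give). Of the listed small nucleolar RNAs, 5 lay inside introns, each on the strand of its host: snR18 in EFB1, snR24 in ASC1, snR38 in TEF4, snR39 in RPL7A and snR44 in RPS22B, all hosts being genes of ribosomal or ribosome-associated proteins or of translation factors. Gaps of 1 nt between exons occurred in EST3, a telomerase subunit gene, and ABP140, an actin-binding protein gene, both known for programmed frameshifting.

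The annotation listed 2999 of the 6021 coding genes of the reference (49.8%), and the share differed by class. All 138 cytosolic ribosomal protein genes, 33 proteasome genes, 23 ergosterol genes and 10 histone genes were listed. Of 70 DNA-binding transcription factors 22 were listed (31.4%, 95% Wilson interval 21.8 to 43.0%, Fisher's exact test, adjusted p = 0.0033), and of 25 cell cycle regulators 11 (44%, 26.7 to 62.9%, adjusted p = 0.739). At the 3' end, 104 of 2882 UTRs (3.61%) ran into coding sequence of a listed gene on the other strand. Genes omitted from the annotation could not be counted, so this share and those that follow are lower bounds. The share was 11.2% (6.67 to 18.2%) of the 116 UTRs of at least 300 nt and 3.29% of the 2766 shorter ones. CYC1 was among them, its 892 nt 3' UTR covering 673 nt of UTR1 coding sequence.

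Some long 5' UTRs may hold intron sequence. A donor and branch point motif lay upstream of 39 genes, and the listed 5' UTR started within 1 nt of the donor in 9 of them (RPS8A, RPS22B, RPL32, ARF2, BMH2, RPS8B, RPS26B, RPS29A and SUN4), against at most 1 in 1000 shuffles of 5' UTR length. It reached the donor in 17, 11 of them ribosomal protein genes, against at most 3 in the shuffles. For the same motifs on the reverse strand the count was 0. That count measured distance from the far end of the upstream window, not from the start codon, so it cannot serve as a control. Intron sequence does not account for all long 5' UTRs, since 17 of the 76 of at least 300 nt reached a donor (22.4%, 14.5 to 32.9%), below the 57.8% (50.9 to 64.3%) of coding introns in the reference that hold the pair of motifs. BRE5, CDS1, IPT1 and GCN4 did not reach one, and no biological explanation was tested.

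Of the 224 convergent overlaps, 221 were between pairs adjacent in the reference, as were all 9 divergent ones. A pair with an omitted gene between its members could hardly overlap. These counts therefore cannot decide whether pairs that skip omitted genes contribute to the excess overlap of convergent mRNAs. The difference from divergent pairs was 51.7 percentage points among pairs adjacent in the reference, a restriction that could hardly lower it. Overlap with the omitted genes themselves could not be counted. Shuffling 3' UTR lengths among the genes of convergent pairs gave overlap in 25.9% of pairs on average (central 95% of shuffles 24.3 to 27.6%), against 29.1% observed. The observed share lay above that range, as it did among pairs adjacent in the reference (53.8% against 47.2 to 52.6%). By the rule set before the test, lengths that take no account of the neighbour thus did not account for all of the overlap. The shuffles reached most of it, while the excess of the observed share over them stays open. How the UTR ends were set is not given in the sources used here and could contribute, and no biological explanation was tested.

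The longer 3' UTRs of respiratory chain and ATP synthase mRNAs did not rest on a few members. Without CYC1, COX6, RIP1, ATP17 and QCR9, the 5 longest, the difference in mean log2 length was 0.75 (SE 0.13, permutation p = 5e-05). Nor did short coding regions account for it, as it was 0.96 (SE 0.17, permutation p = 1e-05) among coding regions of 900 nt or less. Expression level and the way UTR ends were called stay open, and no biological explanation was tested.

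A hypothesis that duplicated ribosomal protein genes share UTR lengths was tested on 57 pairs of copies, 53 of which have coding regions of the same length. The 3' UTR lengths of the copies showed no correlation past the threshold (Spearman rho -0.12, permutation p = 0.379), and the copies differed by a median of 1.67-fold. For the 5' UTR, rho was 0.17 (54 pairs, permutation p = 0.21), whereas Pearson r of log2 lengths was 0.57 (permutation p = 8e-05) and 0.42 without the 2 pairs farthest from the median. Which copy is called A and which B is arbitrary.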
